A study of Homo sapiens with 10 samples.

How the data were processed

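Total RNA of AsPC-1 cells was prepared with a column kit, and libraries were made with the QIAseq UPX 3' Transcriptome kit, which tags transcripts near their 3' ends. The 10 libraries, 5 from cells in complete medium and 5 from cells in glutamine-free medium with 10% dialysed serum, both for 24 h, were grouped by their labels. The aligner, the counting program, the annotation release, the use of molecular identifiers and the use of strand are not given in the sources used here. The submitters' processing notes name the human build hg19. Only the processed expression file was used here; sequencing reads were not analysed here.

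The deposited values are CPM, counts scaled to a common sum per library. Each column summed to 1000000 over 36498 genes, and 100% of the values above 0 were whole multiples of the smallest value of their column, within a relative tolerance of 1e-06. Dividing by that value gave whole counts, 141763 to 474619 per control library and 164008 to 593248 per starved library. A count was worth 1.69 to 7.05 CPM, so that 3 counts in a library, used as the floor, lie between 5.06 and 21.2 CPM. At 0 counts over a group, the floor was 3 counts over the group, 1.85 CPM for control and 2.20 CPM for starved libraries. Of the genes in the file 10633 were at 0 in all libraries, and 555 symbols occurred more than once, so genes were kept apart by their identifiers.

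The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1), two-sided, without covariates, over the 11202 genes with a mean of at least 5 CPM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Preset gene lists, 30 in number with 778 different genes, were written before the data were examined. They were tested with camera (limma) at its preset correlation of 0.01, adjusted over the 25 lists with at least 5 tested genes, with camera at an estimated correlation and with fry beside it. They cover EMT transcription factors, epithelial and mesenchymal genes, the ATF4 response, amino acid transporters, tRNA synthetases, glutamine and serine metabolism, nucleotide synthesis, glycolysis, lipid synthesis, MondoA and NRF2 targets, the respiratory chain, mitochondrial transcripts, ribosomal proteins and ribosome biogenesis. They also cover autophagy, heat shock and endoplasmic reticulum proteins, cell cycle genes, p53 targets, ERK, NF-kB and interferon genes, and markers of acinar, fibroblast, leukocyte and endothelial cells. Of the 14 called lists 10 held with the estimated correlation, and fry, which does not compare with other genes, called 23.

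Named genes followed a rule set before the data were examined: every EMT factor of the list with a count above 0; the 10 largest rises and the 10 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between groups; and up to 4 members of each list with the smallest p, 130 genes in all. Some of these genes are not reported here. Genes named outside this rule are marked as chosen after their values were seen. EMT factors and 5 library measures (total counts, genes above 0, and the shares of the 50 highest genes, of mitochondrial mRNA and of ribosomal protein mRNA) were compared with two-sided exact permutation tests and adjusted by Benjamini-Hochberg within each family. For 5 against 5 libraries the smallest p is 0.00794.

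Alternatives were other pseudocounts (0.5 and 5), no filter and a filter at 20 CPM, TMM, median-of-ratios and quantile scaling, robust empirical Bayes, array weights, an exact rank test, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered counts, a replicate block and leaving out each library in turn. Control replicates 1 and 2 carry library indices 76 and 88, apart from the run of indices in steps of 12 over the others. They were therefore left out together, and a term that sets them apart from the other libraries was fitted; these are nearly the same alternative, as both take the group difference from the other 8 libraries. Thinning all libraries to 141763 counts and edgeR on the 4212 genes kept by filterByExpr were added after seeing the data. The edgeR biological coefficient of variation was 10.2%.

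The methods were tested on simulated data of the same depth, in 1 run with and 1 without changed genes. All genes had 1 dispersion, far fewer genes were changed than were called here, and as many were raised as lowered. Recovery was counted over the changed genes that passed the filter, 50 for each size of rise and 43 for each size of fall. Of these, limma recovered 50.0% of genes raised 2-fold and 92.0% of genes raised 4-fold. It recovered 25.6% of genes lowered to 0.5 and 55.8% of genes lowered to 0.25 of their level. Of its 107 calls 1 was false, and it made 0 calls without a change. edgeR recovered 64.0%, 98.0%, 39.5% and 76.7%, with 5 false calls of 136, and also made 0 calls without a change. From a like control level, falls were thus harder to detect than rises in these runs, as lowered genes end with fewer counts. The shares of false calls hold for these simulated settings and not for the comparison of starved with control cells.

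GENCODE release 29 was used for gene types, for the order of neighbouring genes and for overlaps, and 11135 of the 11202 tested genes (99.4%) were matched to it by identifier. That release uses a later build than the one in the submitters' notes, so no coordinates are given. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and for plots.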

Results

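Gene expression was measured in AsPC-1 cells, an established line from a human pancreatic ductal adenocarcinoma, after 24 h in complete medium (control, 5 libraries) or in glutamine-free medium (glutamine starved, 5 libraries). The series title names Slug, the transcription factor encoded by SNAI2, and epithelial-mesenchymal transition (EMT), so the comparison asks which transcripts, and which EMT regulators among them, differ between fed and starved cells. The libraries came from a kit that reads the 3' ends of transcripts. Counts recovered from the deposited values ranged from 141763 to 474619 per library in control cells and from 164008 to 593248 in starved cells. Their means did not differ detectably between the groups (two-sided exact permutation p = 0.595), nor did the mean number of genes above 0 (p = 0.548). The median count was 395645 in control and 201642 in starved libraries. Starved replicate 1 held 593248 counts and the other starved libraries 164008 to 215121, so the test of means could miss a difference in depth. The 50 highest genes of each library took 20.8% ± 1.17 in control and 22.9% ± 1.05 in starved libraries (two-sided exact permutation p = 0.0159, 0.0265 adjusted over 5 library measures). Without control replicates 1 and 2 together the permutation p of that share was 0.0536, unadjusted, in a range of 0.0159 to 0.0536 over the alternatives. A single count equals 1.69 to 7.05 CPM (counts scaled to a library sum of 1000000), depending on the library. Levels below are means ± SD in CPM (n = 5 per group), and fold changes are of those means. Where a group holds few counts, the ratio of pooled CPM is given with its exact binomial 95% interval. These intervals, and the floors for groups at 0, cover counting error only.

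Glutamine-starved cells carried 15.5 times as much SNAI2 transcript as control cells, with more mRNA of the amino acid stress factors ATF4 and DDIT3, of ERK-responsive and NF-kB genes, of autophagy genes and of transfer RNA synthetases. They carried less mRNA for DNA replication, mitosis, nucleotide synthesis and heat shock proteins, and less of the keratins KRT8 and KRT18. Of 11202 genes with a mean of at least 5 CPM, 4850 changed at an adjusted p under 0.05 (limma-trend on log2(CPM + 1), Benjamini-Hochberg), 1929 higher and 2921 lower in starved cells. The first principal component of these genes held 47.0% of the variance and separated the groups. In 3409 genes (30.4%) the libraries of the groups did not overlap, against 0.794% by chance. The median log2 change of all tested genes was -0.22. Quantile normalization moved that median by 0.21 to -0.02, and TMM scaling by 0.08 to -0.14. Gene lists were compared with all other tested genes (camera, a test set beforehand), which takes out such a shared shift. Of 30 lists 25 had at least 5 tested genes, and 14 of them stood apart, 5 toward higher and 9 toward lower levels. With an estimated correlation 10 held, 5 toward higher and 5 toward lower levels; the 4 lost ones, respiratory chain, mitochondrial transcripts, NRF2 targets and serine and one-carbon synthesis, were all toward lower levels. With TMM, median-of-ratios or quantile scaling no list turned its direction.

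**Figure D1:**
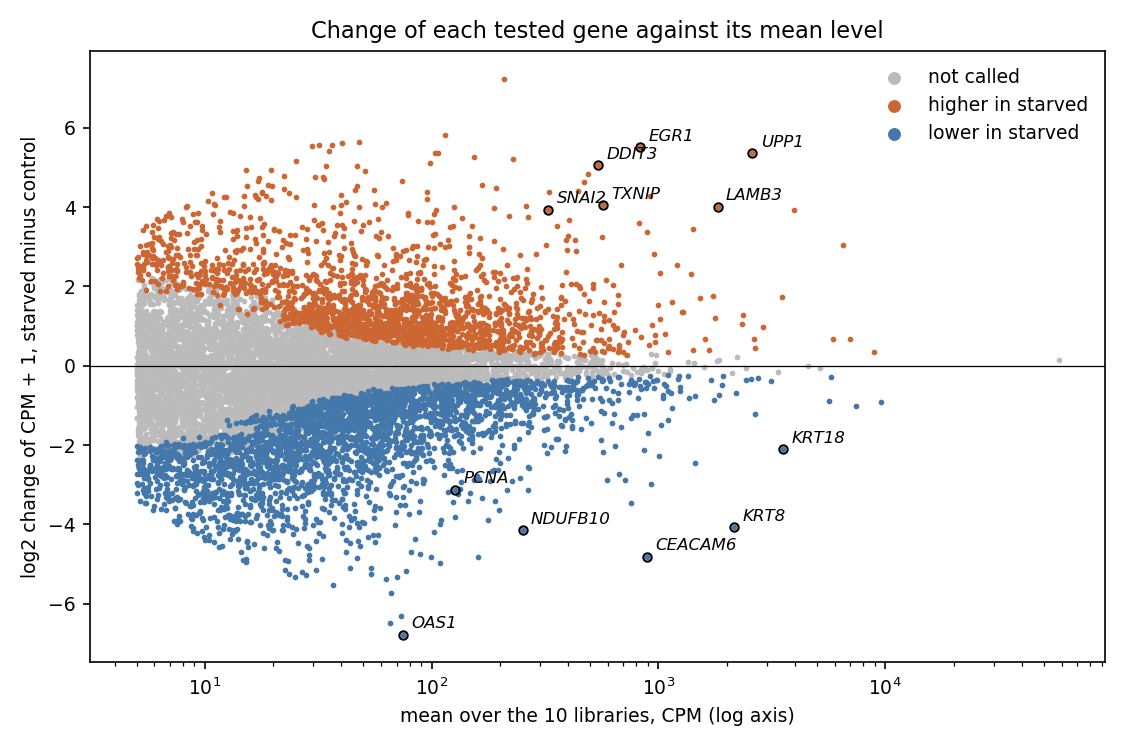
Log2 change of CPM + 1 in starved minus control libraries (vertical axis) against the mean CPM over the 10 libraries (horizontal, log axis) for 11202 tested genes. Orange points are the 1929 genes called higher and blue points the 2921 called lower; SNAI2, DDIT3, TXNIP, EGR1, LAMB3 and UPP1 are marked among the higher genes, and KRT8, KRT18, CEACAM6, OAS1, PCNA and NDUFB10 among the lower ones.

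SNAI2 (ENSG00000019549.8) rose from 39.6 ± 8.22 to 613 ± 65.9 CPM (log2 change 3.93, SE 0.15, limma adjusted p = 8.6e-15). Its highest control library held 54.1 CPM and its lowest starved library 560.4 CPM. ZEB1, another EMT transcription factor, rose from 109.7 ± 22.2 to 178 ± 18.7 CPM (log2 change 0.71, SE 0.16, limma adjusted p = 0.00149); it overlaps an antisense gene, ZEB1-AS1, that was not called, so its reads cannot be fully assigned without knowing how strand was used. Of the 12 EMT factors in the preset list 11 are in the file, and these 2 were the only tested ones. SNAI1, SNAI3, PRRX1 and FOXC2 had 0 counts in all 10 libraries, where 3 counts over a group, the floor used here, correspond to 1.85 CPM in control and 2.20 CPM in starved cells. TWIST1 had 1 and 1 counts over the 5 control and the 5 starved libraries, TWIST2 1 and 2 counts, ZEB2 2 and 4 counts, TCF4 5 and 2 counts and KLF8 0 and 1 counts, so changes in them were not detectable at this depth. In two-sided exact permutation tests adjusted over these 7 factors, SNAI2 and ZEB1 both reached p = 0.0278, from the smallest p that 5 against 5 libraries allow (0.00794), and the other 5 factors gave adjusted p from 0.778 to 1.

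Epithelial genes fell on balance: of 25 tested, 13 fell and 4 rose (4 up and 13 down, adjusted over the list alone; camera adjusted p = 0.00390 with limma's preset correlation). KRT8, a keratin of simple epithelia like KRT18 and KRT19, fell from 4075 ± 92.7 to 244 ± 20.8 CPM (16.7-fold; log2 change -4.06, SE 0.08, limma adjusted p = 2.2e-19), KRT18 from 5734 ± 409 to 1341 ± 157 CPM and KRT19 from 1578 ± 56.9 to 616 ± 47.7 CPM. CEACAM6, a cell surface adhesion glycoprotein, fell from 1714 ± 148 to 66.2 ± 34.5 CPM (25.9-fold). KRT8 overlaps KRT18 in the annotation, the keratins have many pseudogenes and CEACAM6 has close paralogs, so their exact levels are uncertain. The 4 members that rose were TJP1, CRB3, CLDN1 and PKP2, genes of tight junctions, polarity and desmosomes, named after their values were seen; TJP1 went from 106 ± 19.3 to 408 ± 56.4 CPM. CDH1, which encodes E-cadherin and was also chosen after its values were seen, was not called, with 35.4 ± 12 in control and 19.1 ± 4.69 CPM in starved libraries. Its mean was lower in starved libraries, and limma recovered only 25.6% of simulated falls to 0.5, so a fall of CDH1 is not excluded.

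Mesenchymal and invasion genes went both ways, with 9 of 21 tested members higher and 9 lower (9 up and 9 down, adjusted over the list alone), and the list did not stand apart from other genes (camera adjusted p = 0.0939). Without a filter it did (camera adjusted p = 0.0245), in a range of 1.7e-05, given by fry, to 0.352 over the alternatives. LAMB3 and LAMA3, which encode basement membrane laminin chains, rose, LAMB3 from 213 ± 23.6 to 3433 ± 320.2 CPM and LAMA3 from 176 ± 21 to 571 ± 29.7 CPM. TPM1, an actin-binding tropomyosin, fell from 222 ± 29.5 to 36.7 ± 15.1 CPM. VIM, the mesenchymal intermediate filament gene, fell from 2088 ± 266 to 1745 ± 117 CPM (log2 change -0.25, SE 0.09, limma adjusted p = 0.0271), close to the median shift of all genes, and was not called with edgeR (adjusted p = 0.179). CDH2, which encodes N-cadherin, did not reach the mean of 5 CPM needed for testing; it and VIM were chosen after their values were seen.

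**Figure D2:**
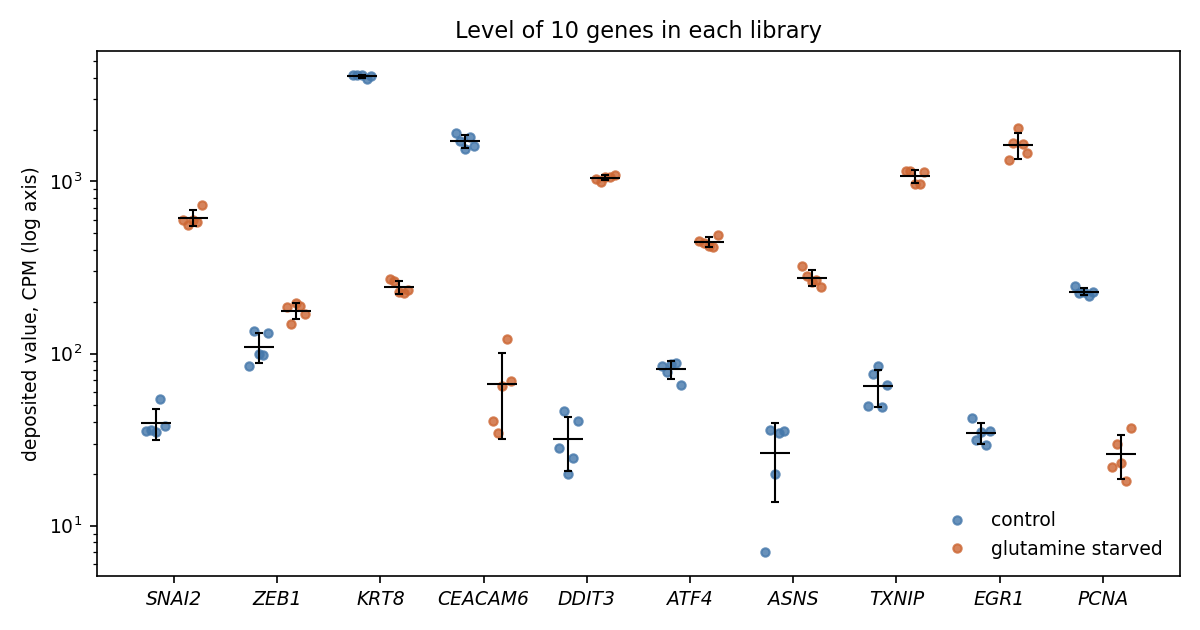
Deposited CPM (vertical, log axis) of 10 genes in each of the 5 control (blue) and 5 glutamine-starved (orange) libraries, with horizontal marks and error bars for the mean and SD. For all 10 genes the points of the groups do not overlap; SNAI2 lies between 34.8 and 54.1 CPM in control and between 560.4 and 727 CPM in starved libraries.

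Genes of the response to amino acid shortage rose together. Of 28 tested ATF4 and amino acid response genes 21 rose and 2 fell (22 up and 2 down, adjusted over the list alone; camera adjusted p = 5.6e-09). DDIT3, which encodes the stress factor CHOP, rose from 31.9 ± 11.1 to 1049 ± 34 CPM (32.9-fold; log2 change 5.06, SE 0.18, limma adjusted p = 1.8e-15); MARS and MBD6, which overlap it on the opposite strand, rose far less. ATF4 itself rose from 80.8 ± 9.34 to 443 ± 28.8 CPM, and its target TRIB3, a pseudokinase, from 17.2 ± 10.4 to 366 ± 43.5 CPM. The members that fell were EIF4EBP1, a repressor of cap-dependent translation, and SLC7A11, the cystine importer, which is also in the NRF2 list; EIF4EBP1 was named after its values were seen. SLC7A11 went from 96.1 ± 14.4 to 22.1 ± 5.89 CPM. Transfer RNA synthetases of the cytosol rose on balance, 11 of 20 up and 2 down (11 up and 2 down, adjusted over the list alone; camera adjusted p = 0.00658), with AARS from 66.5 ± 19.3 to 309 ± 28.4 CPM and SARS from 105 ± 11.9 to 313 ± 46.3 CPM, while KARS fell from 178 ± 26.8 to 72.8 ± 13.8 CPM. Among amino acid transporters, 5 of 14 rose and 2 fell (5 up and 2 down, adjusted over the list alone). SLC3A2, the heavy chain shared by several exchangers, rose from 160.5 ± 34.3 to 663 ± 37 CPM and SLC38A2, a glutamine carrier, from 358 ± 32.9 to 913 ± 58.7 CPM. As a list the transporters missed the threshold (camera adjusted p = 0.0559), as they did in 17 of 23 alternatives. With camera the list passed without starved replicate 2 (adjusted p = 0.0471), at a pseudocount of 0.5 (0.0496) and without a filter (0.0180). It also passed with a filter at 20 CPM (0.0236) and after thinning (0.0276). Over the alternatives its adjusted p ran from 5.9e-05, given by fry, which does not compare with other genes, to 0.128.

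Genes of glutamine, glutamate and hexosamine metabolism split evenly, 6 of 21 up and 6 down (6 up and 6 down, adjusted over the list alone; camera adjusted p = 0.774, direction up, whereas the median log2 change was -0.69 and the mean -0.21). ASNS, asparagine synthetase, rose from 26.5 ± 12.8 to 275 ± 28.8 CPM. The transaminases parted: the cytosolic GOT1 rose from 49.2 ± 20.8 to 232 ± 52.3 CPM, and the mitochondrial GOT2 fell from 81.2 ± 17.6 to 16.2 ± 5.74 CPM. In serine, glycine, one-carbon and proline synthesis 7 of 13 genes fell and 1 rose (1 up and 8 down, adjusted over the list alone; camera adjusted p = 0.0240). That call was lost at camera adjusted p = 0.135 with an estimated correlation. Over the alternatives the adjusted p ran from 1.2e-05, given by fry, which does not compare with other genes, to 0.135. SHMT1, the cytosolic serine hydroxymethyltransferase, had 45 and 0 counts over the control and starved libraries, at least 12.6-fold lower in starved cells against a floor of 3 counts over the group. MTHFD2 and PSAT1, chosen after their values were seen, were not called; MTHFD2 had 91.8 ± 17 in control and 72.6 ± 16.5 CPM in starved libraries. Glucose-sensing MondoA targets had 4 tested members, too few for a list test; 3 of them rose (3 adjusted over the list alone). TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose from 64.9 ± 15.7 to 1072 ± 97.1 CPM, and ARRDC3 from 20.7 ± 8.96 to 227 ± 33.3 CPM.

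ERK-responsive genes rose, 16 of 22 up and 4 down (16 up and 4 down, adjusted over the list alone; camera adjusted p = 2.2e-06). EGR1, an immediate early transcription factor, rose from 34.7 ± 4.87 to 1628 ± 271 CPM, FOSL1, a subunit of AP-1, from 338 ± 51.3 to 1699.7 ± 255 CPM, and the EGF receptor ligand AREG from 58.6 ± 12.3 to 747 ± 54.1 CPM. The 4 that fell were CCND1, the cyclin D1 gene, the feedback inhibitor SPRY1 and the transcription factors ETV1 and ETV4, named after their values were seen. Of NF-kB inflammatory genes 8 of 14 rose and 2 fell (8 up and 2 down, adjusted over the list alone; camera adjusted p = 0.00692), with NFKB2 from 5.26 ± 3.13 to 58.1 ± 10.4 CPM. The chemokine gene CXCL8 rose, with 3 and 90 counts over the control and starved libraries. Interferon response genes split, 6 of 24 up and 11 down (6 up and 11 down, adjusted over the list alone; camera adjusted p = 0.416). OAS1, an enzyme that senses double-stranded RNA, fell from 245 to 2 counts, whereas HLA-E rose from 47.3 ± 14.5 to 222 ± 49.1 CPM. HLA-E and the falling IFITM1 have near-identical relatives, so their levels are uncertain.

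Proliferation genes fell together. Of 38 tested S-phase and DNA replication genes 35 fell and 0 rose (35 down, adjusted over the list alone; camera adjusted p = 1.4e-09). PCNA, the sliding clamp of DNA polymerases, fell from 229 ± 11.3 to 26.1 ± 7.45 CPM (8.77-fold; log2 change -3.12, SE 0.21, limma adjusted p = 8.9e-11), and the helicase subunit MCM6 from 87.2 ± 18.7 to 10.2 ± 3.87 CPM. Of 34 mitosis genes 25 fell and 3 rose (3 up and 26 down, adjusted over the list alone; camera adjusted p = 0.000651), with the proliferation marker MKI67 from 739 ± 57.2 to 273 ± 27.7 CPM and the kinase PLK1 from 195 ± 15.5 to 46.7 ± 13.4 CPM. Purine and pyrimidine synthesis genes fell in 13 of 20 cases and rose in 0 (13 down, adjusted over the list alone; camera adjusted p = 0.000152), among them PAICS, a purine synthesis enzyme, from 201 ± 23.7 to 59.8 ± 8.03 CPM. TYMS, thymidylate synthase, fell from 105 ± 25.3 to 2.60 ± 2.44 CPM; ENOSF1, which overlaps it on the opposite strand, fell as well. Of 16 p53 targets 5 rose and 3 fell (7 up and 3 down, adjusted over the list alone), and the list did not stand apart (camera adjusted p = 0.122). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 14.2 ± 5.98 to 176 ± 29.4 CPM. MYC rose from 113 ± 32.3 to 313 ± 6.17 CPM and its target ODC1, the first enzyme of polyamine synthesis, from 90.3 ± 21.2 to 1736 ± 55.6 CPM. Ribosome biogenesis and MYC targets as a list were not called, with 6 of 29 up and 14 down (6 up and 16 down, adjusted over the list alone; camera adjusted p = 0.160). Without a filter the list was called (camera adjusted p = 0.0358), in a range of 7.2e-05, given by fry, to 0.236 over the alternatives. NCL, the nucleolar protein nucleolin, fell from 683 ± 143 to 271 ± 49.9 CPM.

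Genes of the respiratory chain encoded in the nucleus fell in 25 of 36 cases and rose in 0 (25 down, adjusted over the list alone; camera adjusted p = 1.4e-05). The camera call was just lost, at adjusted p = 0.0501 with an estimated correlation, in a range of 5.9e-08 to 0.0501 over the alternatives. NDUFB10, a complex I subunit, fell from 475 ± 86.5 to 28.6 ± 14.6 CPM and COX7C, a complex IV subunit, from 596 ± 53 to 233 ± 28.5 CPM. Messenger RNAs of the mitochondrial genome made up 5.20% ± 0.319 in control and 3.38% ± 0.199 in starved libraries (two-sided exact permutation p = 0.00794, the smallest possible; 0.0198 adjusted over 5 library measures). Of these transcripts 10 of 13 fell and 0 rose (10 down, adjusted over the list alone); MT-ATP6 fell from 9877 ± 839.8 to 4902 ± 298 CPM, while MT-ND2, chosen after its values were seen, was not called, with 4577 ± 140.0 in control and 4528 ± 323 CPM in starved libraries. Their camera call (adjusted p = 0.0324) ended at adjusted p = 0.359 with an estimated correlation. It also ended with TMM or median-of-ratios scaling (camera adjusted p = 0.0664 and 0.0619). The same happened without control replicate 2, starved replicate 1 or starved replicate 4 (camera adjusted p = 0.0562, 0.0585 and 0.0524). It happened too without control replicates 1 and 2 together or with a term that sets them apart (camera adjusted p = 0.0563 and 0.0560). Over the alternatives the adjusted p ran from 0.000112, given by fry, which does not compare with other genes, to 0.359.

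Of 20 NRF2 targets 13 fell and 2 rose (2 up and 13 down, adjusted over the list alone). The camera adjusted p was 0.00947, and 0.0560 with an estimated correlation. Over the alternatives the adjusted p ran from 1.4e-06, given by fry, which does not compare with other genes, to 0.0560. AKR1C3, an aldo-keto reductase whose close paralogs make its level uncertain, fell from 239 ± 42.5 to 26.9 ± 4.91 CPM, and the transporter ABCC3 from 184 ± 9.15 to 47.7 ± 16.2 CPM. FTH1, the ferritin heavy chain, which has many pseudogenes, rose from 1385 ± 150.3 to 3344 ± 199 CPM. Glycolysis and hypoxia genes were not called as a list, with 3 of 22 up and 11 down (3 up and 13 down, adjusted over the list alone; camera adjusted p = 0.0719). They were called without a filter, with a filter at 20 CPM and after thinning (camera adjusted p = 0.0226, 0.0395 and 0.0429). Over the alternatives the adjusted p ran from 2.3e-05, given by fry, to 0.236. LDHA, lactate dehydrogenase A, fell from 1408 ± 133 to 326 ± 41.8 CPM and TPI1, a glycolytic isomerase, from 933 ± 35.2 to 207 ± 33.7 CPM, but NDRG1 rose from 14.8 ± 4.84 to 187 ± 41.3 CPM. Fatty acid synthesis and SREBP1 targets (2 of 13 up and 8 down, 2 up and 8 down adjusted over the list alone) and cholesterol synthesis and SREBP2 targets (2 of 22 up and 6 down, 2 up and 6 down adjusted over the list alone) did not stand apart either (camera adjusted p = 0.0956 and 0.668). Without a filter the fatty acid list did (camera adjusted p = 0.0101), in a range of 2.3e-05, given by fry, to 0.192 over the alternatives. SCD, the stearoyl-CoA desaturase, fell from 86.5 ± 19.9 to 24.7 ± 3.99 CPM. HMGCS1, an early enzyme of the mevalonate pathway, rose from 26.7 ± 13.7 to 202 ± 34.7 CPM, as did an antisense gene that overlaps it.

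Autophagy and lysosome genes rose, 14 of 28 up and 4 down (14 up and 4 down, adjusted over the list alone; camera adjusted p = 0.000736). MAP1LC3B, which encodes the autophagosome protein LC3B, rose from 40.7 ± 13.5 to 839 ± 59 CPM, and the cargo receptor SQSTM1 from 339 ± 28.8 to 806 ± 27 CPM. ATG12, needed for autophagosome growth, rose from 74.6 ± 12.4 to 728 ± 50.1 CPM, and overlaps AP3S1 on the opposite strand, which also rose. Heat shock proteins fell, with 9 of 13 down and 0 up (9 down, adjusted over the list alone; camera adjusted p = 0.000936). HSP90AA1 fell from 1372 ± 179 to 426 ± 63.9 CPM and HSPB1, a small heat shock protein, from 366 ± 20.8 to 31.2 ± 14.6 CPM. Chaperones of the endoplasmic reticulum and unfolded protein response genes went both ways, 8 of 24 up and 7 down (8 up and 7 down, adjusted over the list alone; camera adjusted p = 0.463). Their median log2 change was -0.10, while the mean was 0.11 and the camera direction up. HSPA5, which encodes the chaperone BiP, rose from 336 ± 36.9 to 984 ± 33.8 CPM, and calreticulin, CALR, fell from 297 ± 49.8 to 128 ± 40.0 CPM. Ribosomal protein mRNA made up 5.08% ± 0.318 in control and 4.22% ± 0.237 in starved libraries (two-sided exact permutation p = 0.00794, 0.0198 adjusted over 5 measures). Of 75 tested ribosomal protein genes 29 fell and 3 rose (3 up and 29 down, adjusted over the list alone), and the list was not called against other genes (camera adjusted p = 0.0760). Without control replicate 1 or control replicate 4 it was (camera adjusted p = 0.0308 and 0.0384), in a range of 0.00313 to 0.605 over the alternatives. RPL27 fell from 1038 ± 57.9 to 252 ± 14.1 CPM, more than RPS20, which fell from 1733 ± 189 to 983 ± 56.9 CPM; many of these genes have processed pseudogenes, so their levels are uncertain.

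**Figure D3:**
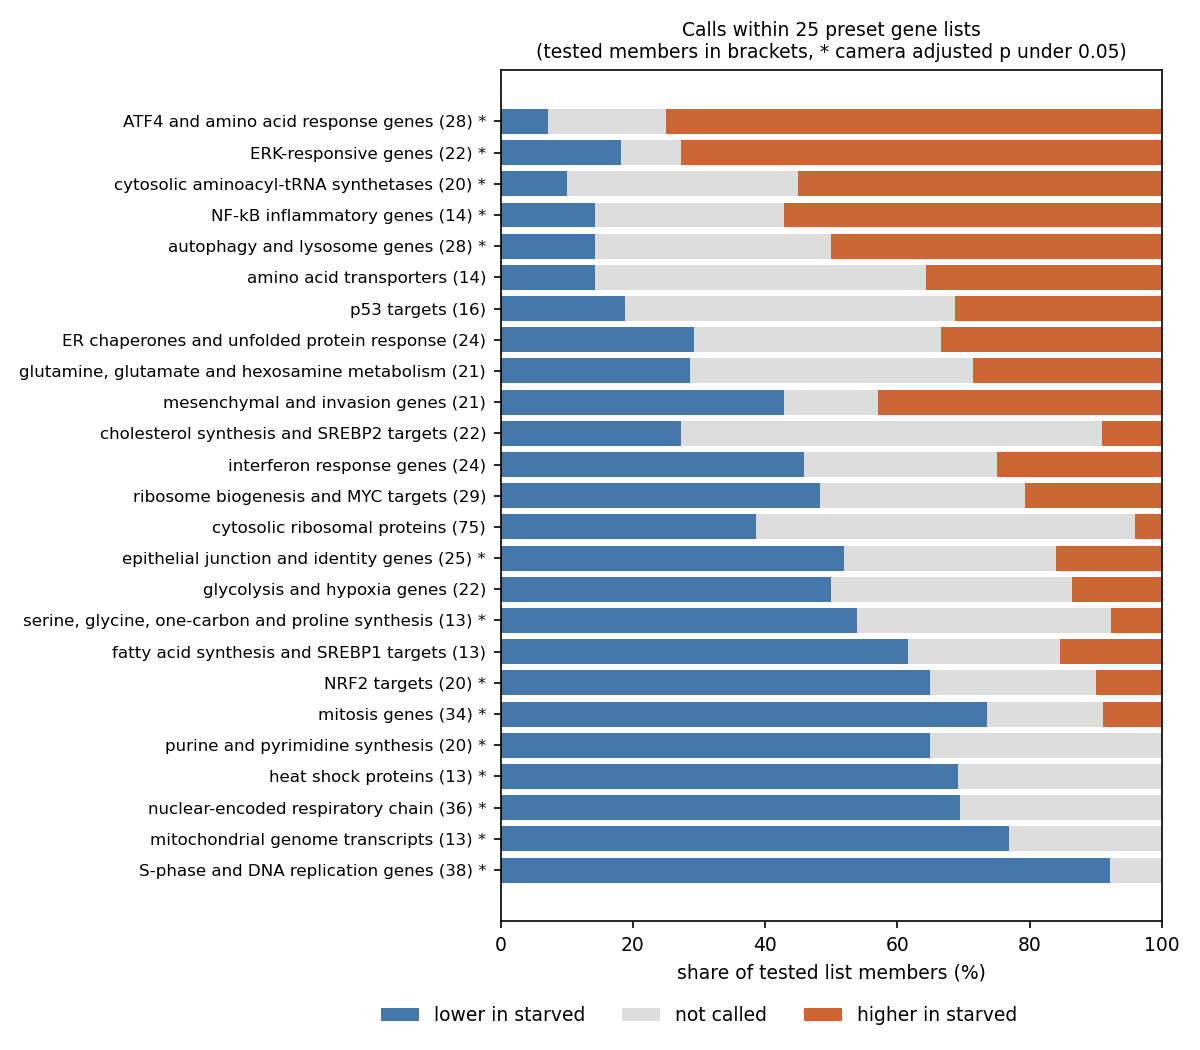
Share of tested members (horizontal axis, percent) called lower (blue), not called (grey) and called higher (orange) in starved cells for the 25 lists with at least 5 tested members, which are given in brackets; an asterisk marks the 14 lists with a camera adjusted p under 0.05. S-phase genes, with 35 of 38 lower, stand at the bottom, and ATF4 and amino acid response genes, with 21 of 28 higher, at the top.

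Among genes with a mean of at least 20 CPM in the higher group and no overlap between groups, the 10 largest rises in log2(CPM + 1) included the immediate early gene EGR1, SESN2 (a stress-induced inhibitor of mTORC1 signalling, from 6.22 ± 5.77 to 206 ± 26.9 CPM) and PER1 (a circadian clock gene). They also held DUSP10, a phosphatase of stress kinases, AGPAT4, a lysophospholipid acyltransferase, and C7orf57. PER1 had 2 and 114 counts over the control and starved libraries, a CPM ratio of 67.7 (interval 18.3 to 566); RP11-599B13.6, which overlaps it on the same strand, rose as well. For DUSP10 the numbers were 2 and 93 counts, a CPM ratio of 55.2 (interval 14.9 to 463). AGPAT4 had 1 and 97 counts and a CPM ratio of 115 (interval 20.2 to 4595), and C7orf57 2 and 131 counts and a CPM ratio of 77.8 (interval 21.1 to 649). The remaining 4 were transcripts without a known protein. RP11-676J12.7 rose from 2.76 ± 2.87 to 414 ± 40.6 CPM, and RP5-1029K10.2 from 5.14 ± 4.77 to 225 ± 58.2 CPM; the annotation lists both as antisense genes, so without strand information reads from an opposite gene cannot be excluded. NXN, the tested gene opposite RP11-676J12.7, was not called. AADACP1 and LINC00707 had 1 and 89 counts and 1 and 82 counts, with ratios of 106 (interval 18.5 to 4220.0) and 97.4 (interval 17 to 3892). Some of these ratios rest on a single control library. Without control replicate 1 the ratio of AGPAT4 was at least 35, against the floor of 3 counts over the group, and that of C7orf57 142. It was at least 26.6 for AADACP1 without control replicate 5 and at least 22.9 for LINC00707 without control replicate 2, against the same floor. PER1 reached 102 without control replicate 3, and DUSP10 83 and 83.4 without control replicate 3 or 5.

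The 10 largest falls in log2(CPM + 1) included OAS1, with 245 and 2 counts over the control and starved libraries, a ratio of 103 (interval 28.3 to 857) of control to starved. GCNT3, a mucin glycosyltransferase, had 200 and 3 counts, a ratio of 56.1 (interval 18.9 to 275). PPP1R1B, which encodes the phosphatase inhibitor DARPP-32, had 223 and 2 counts, a ratio of 93.9 (interval 25.7 to 780.2). IFITM1 had 196 and 8 counts, a ratio of 20.6 (interval 10.3 to 48.5), and 93.2 without starved replicate 1, which held most of its starved counts. BMP4, a growth factor gene of the TGF-beta family, had 193 and 4 counts, a ratio of 40.6 (interval 15.6 to 151), and 70.0 without starved replicate 5. NPNT, a matrix protein gene, had 217 and 8 counts, a ratio of 22.8 (interval 11.4 to 53.6), and 51.6 without starved replicate 1. TYMS had 172 and 4 counts, a ratio of 36.2 (interval 13.9 to 134). FAM111B, VWA1 and CDCA7 had 101, 82 and 84 counts over the control libraries and 1 count each over the starved ones, with ratios of 85.1 (interval 14.9 to 3393), 69.1 (interval 12.1 to 2761) and 70.7 (interval 12.4 to 2827). Without starved replicate 1 the starved group had 0 counts of OAS1, GCNT3 and VWA1, and the ratios became at least 38.8, at least 31.7 and at least 13 against the floor of 3 counts over the group. For FAM111B and CDCA7 they became 48 and 39.9 without it. FAM111B without starved replicate 4 and CDCA7 without starved replicate 3 had 0 starved counts, with ratios of at least 24.9 and at least 19.9. The ratio of PPP1R1B was 165 without starved replicate 4.

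Markers of other cell types were sparse, as few were tested. Of 13 fibroblast and stellate cell markers 2 were tested; LUM, a matrix proteoglycan gene, fell from 113 ± 28.5 to 26.3 ± 3.48 CPM, and RGS5 was not called (15.6 ± 1.93 in control and 12.4 ± 8.06 CPM in starved libraries). Of 17 leukocyte and endothelial markers 3 were tested: CD68, a lysosomal protein gene also used by epithelial cells, rose from 43.6 ± 9.02 to 81.8 ± 19.4 CPM, LYZ, lysozyme, fell from 76.4 ± 18.1 to 8.62 ± 3.08 CPM, and VWF was not called (0.994 ± 2.22 in control and 9.56 ± 13 CPM in starved libraries; edgeR adjusted p = 0.0302, in a range of 0.0302 to 0.469 over the alternatives). Of 20 acinar markers 2 were tested: PRSS3, a trypsinogen gene with close paralogs, rose from 231 ± 27.6 to 482 ± 38.9 CPM, and AMY2B was not called (7.25 ± 12.6 in control and 7.93 ± 4.97 CPM in starved libraries). Counts adjusted over the list alone were the same for these 3 lists and for the EMT factors.

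No source says whether the 5 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The labels describe dialysed serum for the glutamine-free medium and not for the growth medium, so the serum may differ between the groups along with glutamine. With a count model (edgeR) limited to the 4212 genes kept by filterByExpr, 2850 genes changed, 1394 higher and 1456 lower.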

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

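The comparison of each library with the other 4 of its group, by the gap to the nearest library over the range of the group (Dixon's test), was fixed before the data were examined. It marked 32 values in 268 groups, and chance marks about 5% of groups. Glutamine-starved replicate 1 held 7 of the marks, starved replicate 4 held 5, and control replicates 1 and 4 held 4 each.

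Starved replicate 1 was the deepest library, with 593248 counts and 17489 genes above 0, against 164008 to 215121 counts in the other starved libraries. SNAI2 was highest in control replicate 4, at 54.1 CPM, and in starved replicate 5, at 727 CPM; both lie on their own group's side of the gap between the groups.

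Many marks rest on 1 to 3 counts where the other libraries of the group held 0. In control libraries these were TWIST1, AADACP1 and CXCL3 at 2.53 CPM in replicate 5, TWIST2 at 2.49 CPM and VWF at 4.97 CPM in replicate 3, AGPAT4 at 7.05 CPM in replicate 1 and LINC00707 at 2.11 CPM in replicate 2. In starved libraries they were KLF8 and VWA1 at 1.69 CPM, OAS1 at 3.37 CPM and GCNT3 at 5.06 CPM in replicate 1, TWIST1 and FAM111B at 6.10 CPM in replicate 4 and CDCA7 at 4.65 CPM in replicate 3. TWIST2 and PPP1R1B, at 6.10 CPM in starved replicate 4, also stood at a single count, with at most 1.69 CPM in the others.

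Among genes with more counts, control replicate 1 was highest for TRIB3 (35.3 CPM) and GOT1 (84.6 CPM) and lowest for XBP1 (21.2 CPM). Control replicate 4 was highest for FDFT1 (182 CPM), TARS (207 CPM) and AMY2B (29.5 CPM). Control replicate 2 was highest for HERPUD1 (56.9 CPM) and RGS5 (19 CPM), and control replicate 3 was lowest for PAICS (159 CPM). Starved replicate 4 was lowest for ACSL3 (165 CPM), starved replicate 3 lowest for LPIN1 (32.5 CPM) and starved replicate 1 highest for AKR1C3 (35.4 CPM).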

How the results depend on the processing

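Thinning to equal totals and edgeR with filterByExpr were chosen after seeing the data; the other alternatives were fixed before. edgeR with filterByExpr called 2850 genes, 1456 of them lower, in fewer genes tested (4212). Over all alternatives 2850 to 5356 genes were called, 4341 to 4649 when a single library was left out, and 0 of the calls shared with the limma result had the opposite sign under any of them. The replicate block gave 4801 genes, with the mitochondrial transcripts at a camera adjusted p of 0.0614. No pairing by replicate number was seen in correlations between control and starved libraries after removing group means. They ran from -0.0158 to 0.0227 for equal numbers and from -0.0317 to 0.0289 for others, and 1 library matched its own number best. Correlations this small in shallow libraries cannot exclude a shared culture or day. Among lists, fry called 23, because it does not compare with other genes; the estimated correlation left 10, and leaving out a single library 13 to 15. Of 14 called lists 10 kept their call under every alternative run on them, and 9 of 11 others were called under at least 1; no list changed direction. SNAI2 stayed at a log2 change of 3.80 to 4.29 (3.87 to 4.05 without a single library), ZEB1 at 0.62 to 0.80. Of 120 called named genes 119 kept their call; SLC7A7 lost it when thinned. ARRDC2, not called, had a log2 change of -0.071 when thinned, the reverse of its sign otherwise; the cause was not tested. Other splits of the 10 libraries into 5 and 5 were compared with the real one. For genes 1 of 100 splits, the real one, called 4850, and the highest other called 0. For lists 1 of 100 splits, again the real one, reached 14, and the highest other reached 13. The real split thus gave the most calls of the 100. Every other split still parts the groups unevenly, so its counts are not free of the difference between them. They therefore do not measure how many calls chance alone would give. Depth limits falls and rises alike where 1 group is low, as a group mean under about 5 CPM rests on a few counts.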

Other observations

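The tests of transcription past UPP1, of chance neighbourhood and of a fixed share of UPP1 reads were chosen after the results were seen. UPP1, SUN3, HUS1, ABCA13, TNS3 and FIGNL1 were chosen after their values were seen. The other tests were written before their results were seen.

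UPP1, which encodes a uridine phosphorylase, rose from 124 ± 24.1 to 5068 ± 211 CPM (n = 5 per group; log2 change 5.36, limma adjusted p = 2.4e-19). Genes beside it rose too: SUN3 from 12.8 ± 9.04 to 445 ± 25 CPM, C7orf57 from 1.83 ± 3.06 to 93.9 ± 14.2 CPM and HUS1 from 37.4 ± 5.79 to 129 ± 21.8 CPM. ABCA13, the next tested gene on the 3' side of UPP1, was not called (log2 change 1.71, SE 0.74, limma adjusted p = 0.0657). It had 10 and 23 counts over the control and starved libraries. Farther genes on either side, TNS3 and FIGNL1, fell.

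The rise of SUN3 and C7orf57 beside UPP1 was weighed against 3 explanations. Transcription running past the 3' end of UPP1 is excluded by the order of the genes in the annotation, where 0 of this pair lie on the 3' side of UPP1. Chance neighbourhood is not excluded, since 6.15% of 10000 shuffled gene orders held a run of 3 adjacent genes among the 200 most raised; of 13 such adjacent pairs 11 lay elsewhere, a number that 9 of 10000 shuffled orders of the other genes reached. A fixed share of UPP1 reads counted on the neighbours is not excluded for SUN3, but the test cannot tell it from a rise of SUN3 itself. SUN3 and UPP1 rose by a like fold (log2 change 5.22 and 5.36), and any such pair gives a quotient near 1. The ratio of SUN3 to UPP1 counts was 8.37% in control and 8.83% in starved libraries, a quotient of 1.05 (interval 0.637 to 1.86). For C7orf57 the quotient was 1.96 (interval 0.525 to 16.5). That interval includes 1 as well, but it rests on 2 control counts and is too wide to decide the question for C7orf57. Rising transcription of the whole neighbourhood in starved cells is a further hypothesis, not tested here.

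Long intergenic noncoding genes were raised more often than coding genes of like mean expression over both groups. Of 207 tested, 44 (21.3%) were raised, against a central 95% of 6.28% to 14% in 10000 draws of coding genes matched on mean level. A low mean level over both groups is thus excluded as the whole cause. That mean includes the starved level, which itself decides whether a gene is raised. The level in control cells alone was not matched, so these draws cannot exclude a low control level as the cause. Without the long intergenic genes beside a raised gene, 26 of 143 (18.2%) were raised, against 5.59% to 15.4% in draws matched alike. Reads of a raised neighbour are thus excluded as the whole cause of the excess over such draws. Other noncoding types were not matched on level, so whether the excess is particular to long intergenic genes was not tested. Raised were 18.5% of 249 antisense genes and 18.6% of 70 transcribed unprocessed pseudogenes, but 6.37% of 267 processed pseudogenes and 7.32% of 41 small nucleolar RNA genes. Of all tested coding genes, whatever their level, 17.4% were raised. Other technical sources, such as priming inside unspliced RNA of genes farther away, were not tested. A response of long intergenic noncoding genes to starvation may be put forward only as a hypothesis.

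More genes were called lower than higher: 39.8% of the 4850 calls were higher. Shallower libraries in the starved group are excluded as the cause, as the share was 40.4% (interval 38.8% to 42.0%) after thinning to equal totals, under the bound of 45% set before. The intervals of these shares treat called genes as independent and leave out the spread between libraries. When a single library was left out, the share without thinning ran from 37.8% to 41.5%. Scaling by the total count cannot be told apart from a real excess of falls: with TMM scaling the share was 44.8% (interval 43.3% to 46.2%), an interval that includes the bound, and with quantile normalization it was 48.3%. With edgeR it was 46.4%, and higher calls outnumbered lower ones from 50 CPM up (52.7% at 50 to 100 CPM and 54.6% at 100 CPM and above). Whether falls prevail in starved cells therefore stays open.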
